A study of Mus musculus with 25 samples.

How the data were processed

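RNA of 25 liver samples was measured on Illumina bead arrays. Per the labels' protocols RNA was extracted with Trizol, cleaned on RNeasy columns with DNase, and copied into biotin-labelled cRNA with an Ambion MessageAmp kit for Illumina arrays; the array type, the scanner software and the chip of each array are not given in the sources used here. The mice were of C57BL/6J x 129Sv background and were injected with PIK3CA H1047R, PIK3CA E545K or an empty vector, per the labels.

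The non-normalized signals are intensities on a linear scale for each probe and array, called non-normalized per the file headers and name, with different medians on each array and no recorded background subtraction. Beside each stands a detection p-value, made by the scanner software according to its name per the file headers. The authors' processed intensities are on a linear scale with the same distribution on each array, as after quantile normalization; their medians lie between 104.783 and 104.847, they are not centred, and the method is not given in the sources used here. The authors' deposited tables of comparisons hold log2 differences between group means, mean log2 values, and p-values with adjusted p-values over all probes; their columns are those of limma, and version and settings are not given in the sources used here. The log2 scale and direction of the authors' deposited tables were checked against the normalized values made here, described next. Group means of these values match them as the named group minus a control group (correlations of 0.9996 to 0.9998).

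Signals of the 25 arrays were background-corrected and quantile-normalized together with neqc of limma 3.58.1 in R 4.3.3, with background estimated from the detection p-values and an offset of 16. Probes detected at p under 0.05 on at least 4 arrays were kept, 20349 in number. Of all probes 33778 had a gene symbol, 33509 of them through an Entrez identifier with 658 symbols brought up to date, and 11503 had none and were left out. Of the 16981 detected probes with a symbol the one with the highest mean log2 value stood for each gene, which left 11594 genes, 3907 of them with several detected probes. Predicted gene models (396 genes) were tested and counted but are not named. Input was read with the R package data.table, version 1.17.8, and figures drawn with matplotlib 3.10.9.

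Each comparison was a fit of limma (lmFit and eBayes) to its own samples with groups taken from the labels, called at an adjusted p under 0.05 (Benjamini-Hochberg), and genes changed at least 2-fold were counted as well. The comparisons were both mutations at 3 months against the 3-month controls and each other, the E545K tumours against 3-month controls and against E545K at 3 months, the controls of both ages, and the H1047R livers of 6 and 12 months as a group of n = 2 against the 6-month controls. These comparisons, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Of 32 gene lists of liver metabolism, signalling, zonation, sex bias and cell types, 29 had at least 4 tested members and were tested with camera of limma at the preset correlation of 0.01, beside camera with an estimated correlation and fry. Adjusted p-values of lists are over the lists of a comparison. List members were counted by their adjusted p over all genes and by one adjusted over the list alone.

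Genes were named by rule. For each comparison these are the 10 highest and the 10 lowest log2 fold changes among genes that passed with groups that do not overlap, all of them where fewer passed, and where none passed on either side the 5 of smallest p on each side, said not to pass. To these come up to 4 members of smallest p of each list described and Pik3ca in every comparison. Other genes are said to be chosen after their values were seen. Single results of some list members are not reported here; these genes stay in the fits and lists.

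For a gene below detection on all arrays of a group the fold is a lower bound, from the mean of the other group and the lowest detected signal of those arrays; no fold is given where both groups are below detection. Median signals rose from 87.6 on the dimmest array, and arrays with low signals detect fewer probes, so small changes of dim genes are measured less precisely. The number of arrays limits precision further. Simulated data held 100 genes shifted by log2 1 and 100 shifted by log2 2 in the same set. Of those shifted by log2 1 limma recovered 65 for H1047R and 67 for E545K at 3 months and 71 for the tumours. It recovered 59 for the 6-month controls and 1 for the late H1047R livers. Of those shifted by log2 2 it recovered 95, 96, 98, 93 and 48. The other shifted genes ease the adjustment of p-values, so a lone change would be recovered less often.

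Alternatives tried were no background correction, the authors' processed values, no filter, every detected probe on its own, all 25 arrays in a single fit, eBayes with trend and robust, array weights, other control groups, the replicate number as a block, each sample left out in turn, and, chosen after seeing the data, arrays with high muscle or acute-phase signal left out. Splits of the samples into other groups of the same sizes were counted over at most 100 splits. The subset sheets of the authors' tables were not used here, since the full sheets hold every probe.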

Results

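Livers of mice injected with PIK3CA H1047R, PIK3CA E545K or an empty vector were compared on 25 Illumina bead arrays. PIK3CA encodes the catalytic subunit p110 alpha of phosphoinositide 3-kinase. Per the labels the groups were preneoplastic liver 3 months after H1047R (4 arrays) or E545K (5), E545K tumours of 5 months (5), 1 preneoplastic H1047R liver of 6 months, 1 H1047R tumour of 12 months, and normal liver of empty-vector mice of 3 months (4) and 6 months (5). The study's description speaks of 5 controls of 3 months and of controls of 5 months; 4 controls of 3 months and none of 5 months were used here. The labels do not state that each array came from a different animal, so the p-values measure the spread between these samples.

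Between 14536 and 18391 probes were detected per array. The first principal component, with 48.7% of the variance, set the E545K tumours (scores 38.5 to 78.6) and the H1047R tumour of 12 months (78.2) apart from the other arrays (-44.0 to 8.57). Each array's mean correlation with the rest of its group lay between 0.946 and 0.982. The Y-linked gene Ddx3y had log2 signals of 10.3 to 12.4 and Eif2s3y of 8.38 to 10.1, detected on 25 of 25 arrays each. The probe for mouse Pik3ca was detected on 14 of 25 arrays, at log2 4.33 to 5.49, where the lowest detected signals of the arrays were 4.59 to 4.93. The labels do not say which species' sequence was injected, so this probe says nothing about the construct. Throughout, a fold is written as at least N-fold where every array of a group lay below detection, and it was then computed against the lowest detected signal of those arrays.

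**Figure D1:**
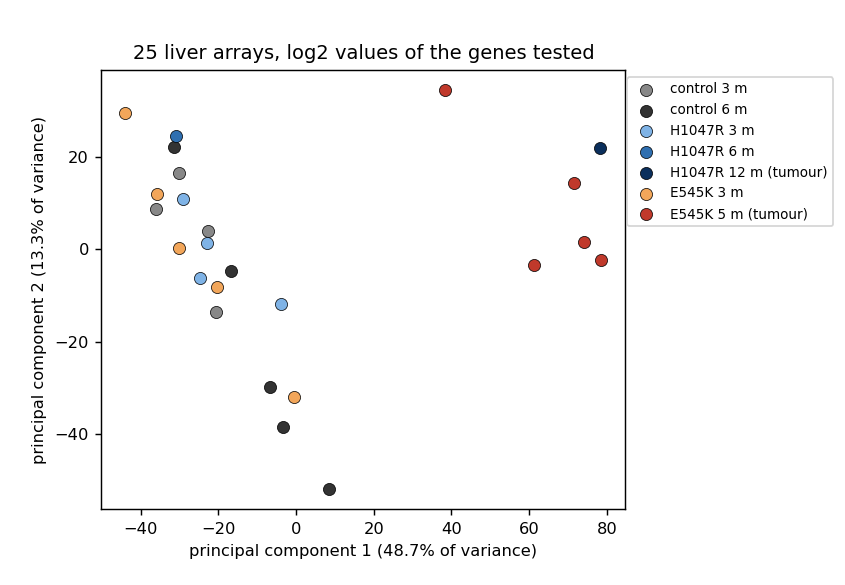
First and second principal components of the log2 values of the tested genes, with the share of variance on each axis (48.7% and 13.3%); each point is an array, coloured by mutation, age and tissue. The E545K tumours and the 12-month H1047R tumour lie to the right of the other arrays.

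In the E545K tumours of 5 months most male-biased liver genes tested were lower, and most oncofetal genes and part of the inflammatory genes tested were higher. Hsd3b5, a male-specific hepatic steroid reductase, was close to background in the tumours, and Lcn2, a siderophore-binding acute-phase protein, was among the brightest genes. Most pericentral and bile acid genes tested were lower, and part of the genes of macrophages, matrix, the oxidative stress factor NRF2 and cell division were higher. Of the 14 lists called, 1 kept its call with an estimated correlation, that of the male-biased genes. The test fry, which asks whether a list moves on balance and compares it with no other genes, called 19 of the 29 lists. Genes of the PI3K-AKT-mTOR pathway went both ways. Of 11594 genes, 4689 passed against the 3-month controls, 2257 higher and 2432 lower. Of these, 1965 changed at least 2-fold (1094 higher, 871 lower) and over all tested genes 3575 had groups that did not overlap, where chance gives 1.59%. Without the 3-month controls with the highest acute-phase means (replicates 1 and 2, left out after the data were seen) 2810 passed, 2663 of them among the 4689, and with the 6-month controls 2309 passed, 1991 of them among the 4689. The tumours, of 5 months, were older than the 3-month controls and younger than the 6-month controls, so age differs with the group.

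Lcn2 rose by 6.85 (SE 0.81, adjusted p = 1.31e-04), from 7.86 (SD 2.30, 4 arrays) to 14.7 (SD 0.10, 5 arrays), which lies among the brightest signals of the tumour arrays, where the scale may flatten, so the size of its folds here and below is rough. Ly6d, a surface protein held by a lipid anchor, rose by 6.70 (SE 0.38, adjusted p = 1.64e-06). So did Spink1 (6.42, SE 0.52, adjusted p = 1.20e-05), a secreted trypsin inhibitor. Akr1c18, which inactivates progesterone, rose by 6.38 (SE 0.45, adjusted p = 4.80e-06). Cpe, a prohormone-processing carboxypeptidase, rose by 6.38 (SE 0.33, adjusted p = 1.08e-06). Rgs16, which shortens G protein signals, rose by 6.22 (SE 0.48, adjusted p = 9.69e-06), but by 2.16 against the 6-month controls (adjusted p = 0.0225), in which it was 4.05 higher than in the 3-month controls. Tspan8, a tetraspanin of epithelial and carcinoma cells, rose by 5.81 (SE 0.65, adjusted p = 9.36e-05). Cyp2b9, a female-biased cytochrome P450, was detected on 0 of 4 control arrays and 5 of 5 tumour arrays and was at least 41.1-fold higher (adjusted p = 3.13e-07). Cbr3, a carbonyl reductase and NRF2 target, rose by 5.61 (SE 0.60, adjusted p = 7.23e-05). Gstp2, a glutathione transferase, rose by 5.39 (SE 0.33, adjusted p = 2.37e-06). Pik3ca itself passed with a rise of 0.57 (SE 0.18, adjusted p = 0.0243), but it was detected on 5 of 5 tumour and 1 of 4 control arrays at 5.10 and 4.53, near background, and against the 6-month controls it had 0.10 (adjusted p = 0.771). The call of Pik3ca also ended without tumour replicates 2, 3 or 5 or control replicates 1, 2 or 4 (adjusted p up to 0.0693). Among the 4 controls Ly6d and Cpe were detected on 2, Akr1c18 on 1 and Rgs16 and Cbr3 on 3, so their folds start near background and are rough.

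On the lower side, Hsd3b5 fell by 7.45 (SE 0.19, adjusted p = 3.51e-09), from 12.1 (SD 0.32) to 4.63 (SD 0.27), and was detected on 1 of 5 tumour arrays. Serpina4-ps1, a serpin pseudogene transcribed in liver, fell by 7.39 (SE 0.42, adjusted p = 1.64e-06). Sult2a8, a hepatic sulfotransferase of bile acids, fell by 5.61 (SE 0.45, adjusted p = 1.13e-05). Elovl3, an elongase of very long fatty acids with male-biased expression, was below detection on all tumour arrays and at least 38.4-fold lower (adjusted p = 4.57e-08). Ces3b, a carboxylesterase, fell by 5.12 (SE 0.46, adjusted p = 2.27e-05). The male-biased fatty acid hydroxylases Cyp4a12b and Cyp4a12a fell by 5.09 (adjusted p = 1.60e-05) and fell by 4.59 (adjusted p = 3.83e-04). Mup9, a major urinary protein, fell by 5.01 (adjusted p = 1.75e-06). Susd4, a complement regulator, fell by 4.96 (adjusted p = 9.22e-06). Myl1, a myosin light chain of skeletal muscle, was at least 33.2-fold lower (adjusted p = 0.00183). Its control level of 9.70 had an SD of 2.82, and the mean of skeletal muscle markers ran from 5.03 to 10.7 over the 3-month controls; against the 6-month controls the call of Myl1 ended (adjusted p = 0.388). Susd4 was detected on 2 and Sult2a8 on 3 of 5 tumour arrays. The Mup, Cyp4a12, Cyp2b and Gstp genes have close paralogs whose transcripts one probe may not separate.

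**Figure D2:**
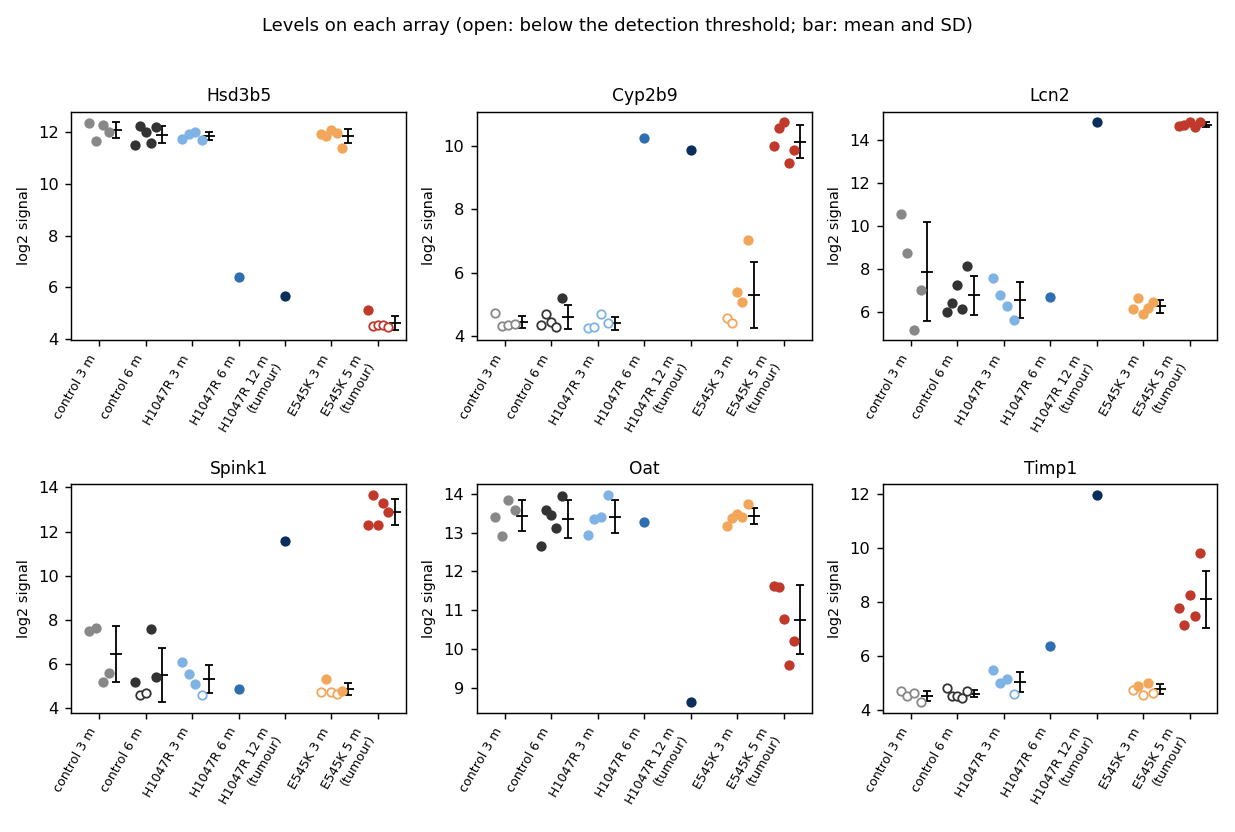
Log2 signal (vertical axes) of Hsd3b5, Cyp2b9, Lcn2, Spink1, Oat and Timp1 on each array, by group; points are arrays, open where the probe was below detection, and bars give mean and SD. Hsd3b5 fell by 7.45 in the E545K tumours and is also low in both late H1047R livers, where Cyp2b9 is high, while Lcn2 is high in the 12-month H1047R tumour and not in the 6-month liver.

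Among the gene lists, the male-biased liver genes showed the lowest median of the lists called against the 3-month controls (-3.28, 0 higher and 11 lower of 12, also 11 adjusted over the list alone; adjusted p = 1.49e-08, adjusted p = 0.0448 with an estimated correlation). Its members include Hsd3b5, Cyp4a12b, Susd4, Cyp7b1 (oxysterol hydroxylase, fell by 3.95) and C8b (complement, fell by 2.30). Female-biased genes had a median of 2.26 with 6 of 8 higher, 7 adjusted over the list alone (adjusted p = 4.79e-04, adjusted p = 0.528 with an estimated correlation), with Cyp2a4 (steroid hydroxylase, 5.39), Abcd2 (peroxisomal transporter, 1.94) and Cyp17a1 (steroid hydroxylase, 2.43, but 0.77 with an adjusted p = 0.367 against the 6-month controls) beside Cyp2b9. Oncofetal genes had a median of 2.94 with 12 higher and 1 lower of 17 (adjusted p = 4.22e-06, adjusted p = 0.103 with an estimated correlation), among them Golm1, a Golgi membrane protein (4.49), Igdcc4, an immunoglobulin-domain receptor (4.60), Ly6d and Akr1c18. Gpc3, a glypican of fetal liver (5.29, adjusted p = 1.59e-04), and Afp, the fetal relative of albumin (at least 9.35-fold higher, adjusted p = 1.60e-05), passed as well and were picked out after their values were seen.

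Many genes of both zonation lists were lower. Of 15 pericentral genes 13 were lower and 0 higher (median -1.87, adjusted p = 5.56e-05, adjusted p = 0.528 with an estimated correlation). Among them were Oat, ornithine aminotransferase (fell by 2.69), Notum and Axin2, feedback inhibitors of Wnt signalling (fell by 2.40 and fell by 1.47) and Rgn, a calcium-binding lactonase (fell by 1.81). Glul, the glutamine synthetase of cells next to the central vein, fell by 2.75 (adjusted p = 0.00377; chosen after its value was seen). Of 11 periportal genes 7 were lower and 1 higher (median -1.19, adjusted p = 0.0305, adjusted p = 0.528 with an estimated correlation), with Ass1 of the urea cycle (fell by 1.22), Cyp2f2 (a periportal P450, fell by 1.80) and Pck1 of gluconeogenesis (fell by 1.19) lower and Ctsc, a lysosomal protease, higher (0.97). The periportal call ended without tumour replicate 1 (adjusted p = 0.0822), without control replicate 2 (adjusted p = 0.0714) and without controls 1 and 2 (adjusted p = 0.151), and that of Ass1 against the 6-month controls (adjusted p = 0.0542). P450 and bile acid genes had 10 of 18 lower and 1 higher (median -1.22, adjusted p = 0.0154, adjusted p = 0.528 with an estimated correlation), among them Cyp27a1 of bile acid synthesis (fell by 1.95). Mature hepatocyte genes as a list did not pass (median -0.11, adjusted p = 0.320), and Alb moved by 0.03 (adjusted p = 0.934; chosen after its value was seen).

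Some genes of stress responses, cell division and glycolysis were higher, in lists that lost their calls with an estimated correlation. NRF2 targets had 7 of 12 higher and 0 lower (median 1.39, adjusted p = 3.61e-04, adjusted p = 0.528 with an estimated correlation), with Nqo1 (quinone reductase, 2.89), Srxn1 (sulfiredoxin, 2.22) and Gstm3 (glutathione transferase, 1.39) beside Cbr3. ATF4 and unfolded protein genes had 8 of 20 higher and 2 lower (median 0.79, adjusted p = 0.0154, adjusted p = 0.528 with an estimated correlation), led by Psat1 of serine synthesis (4.90) with Xbp1 (0.83) and Atf3 (1.03), while Shmt2 of mitochondrial folate metabolism fell by 1.66 on one probe and had 0.34 on another that did not pass. Proliferation genes had 7 of 25 higher and 0 lower (median 0.47, adjusted p = 0.00169, adjusted p = 0.528 with an estimated correlation), with Cdkn3 (cell cycle phosphatase, 2.17), Birc5 (survivin, 1.19), Tyms (thymidylate synthesis, 1.24) and Mki67 (at least 1.95-fold). Glycolysis genes had 5 of 16 higher and 1 lower (median 0.46, adjusted p = 0.0305, adjusted p = 0.528 with an estimated correlation), with Pfkp (at least 2.29-fold), Pklr (1.04), Gpi1 (0.90) and Pgam1 (1.01). Against the 6-month controls the ATF4 list (median 0.44, adjusted p = 0.0642) and glycolysis (0.21, adjusted p = 0.112) did not pass, nor did Xbp1 (0.39), Atf3 (0.51), Tyms (0.88), Pklr (0.16), Gpi1 (0.53) and Pgam1 (0.24). Glycolysis also lost its call without tumour replicate 5 (adjusted p = 0.0589) and without controls 1 and 2 (adjusted p = 0.0697).

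Part of the inflammatory and matrix genes were higher as well, again in lists not called with an estimated correlation. Acute-phase genes had 11 of 18 higher and 0 lower (median 0.89, adjusted p = 2.39e-04, adjusted p = 0.528 with an estimated correlation), among them Lcn2, Il1rn (the interleukin 1 receptor antagonist, 4.26), Cp (ceruloplasmin, 1.30) and Lbp (lipopolysaccharide binding, 1.42). Macrophage markers had 9 of 16 higher and 0 lower (median 1.18, adjusted p = 1.34e-04, adjusted p = 0.528 with an estimated correlation), with Cd63 (a lysosomal tetraspanin, 4.84), Cd14 (the endotoxin co-receptor, 4.03) and the complement genes C1qc (2.63) and C1qb (2.20). Interferon-response genes had 6 of 14 higher and 1 lower (median 0.79, adjusted p = 0.0278, adjusted p = 0.547 with an estimated correlation), with Ifit2 (1.96), Isg15 (1.73) and Cxcl10 (at least 1.47-fold, but an adjusted p = 0.162 against the 6-month controls). The interferon call ended without tumour replicate 1 (adjusted p = 0.138) and without control replicate 3 (adjusted p = 0.0587). Stellate cell and matrix genes had 6 of 17 higher and 2 lower (median 0.55, adjusted p = 0.0133, adjusted p = 0.528 with an estimated correlation), with Timp1, an inhibitor of matrix proteases (at least 10.004-fold), the basement membrane collagens Col4a1 (2.23) and Col4a2 (2.28) and Sparc (2.05). The PI3K-AKT-mTOR list had 5 higher and 6 lower of 25 (median -0.05, adjusted p = 0.880). De novo lipogenesis had 4 higher and 4 lower (median 0.50, adjusted p = 0.256) and fatty acid oxidation 3 higher and 8 lower (median -0.59, adjusted p = 0.0788).

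Of 1847 called genes with several detected probes, 103 had another probe called in the opposite direction and 1020 had another that was not called; among listed genes the former holds for Acaa2 of fatty acid oxidation (fell by 0.57, another probe 2.45).

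**Figure D3:**
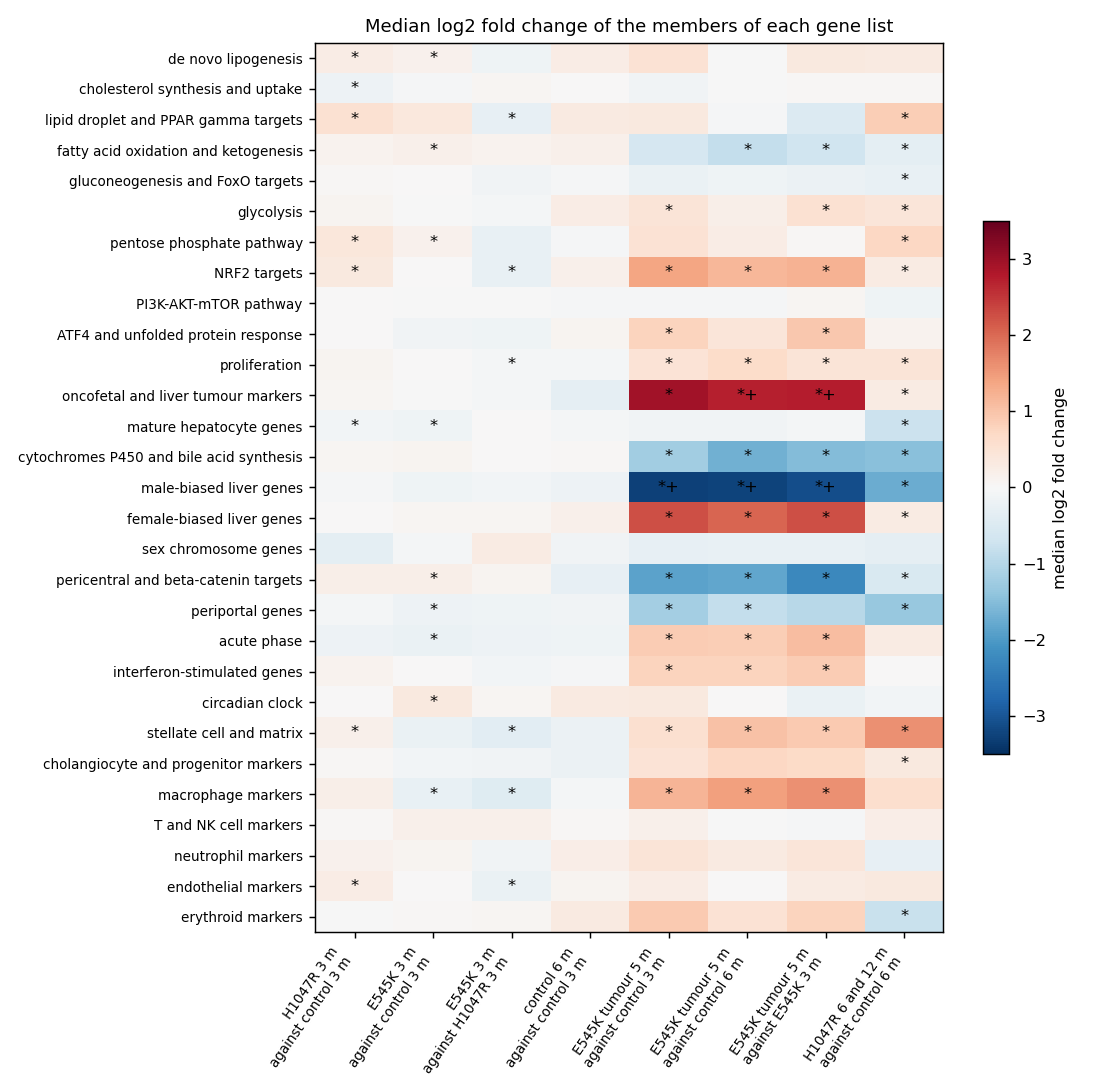
Gene lists (vertical) by comparison (horizontal); colour is the median log2 fold change of a list's tested genes, an asterisk marks adjusted p under 0.05 at the preset correlation and a plus sign the lists also called with an estimated correlation. Male-biased genes (median -3.28 against the 3-month controls) carry the plus sign in each tumour comparison.

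Set against the E545K livers of 3 months, the tumours differed as widely: 4725 genes passed, 2311 higher and 2414 lower, 1854 of them at least 2-fold (1046 higher, 808 lower), and over all tested genes 2718 had groups that did not overlap (chance 0.794%). Lcn2 rose by 8.46 (SE 0.15, adjusted p = 1.44e-11), Spink1 by 8.04 (SE 0.26, adjusted p = 3.37e-09) and Ly6d by 6.71 (SE 0.28, adjusted p = 3.73e-08). H19, an imprinted RNA of fetal liver, rose by 6.19 (SE 1.01, adjusted p = 7.43e-04) with an SD of 2.74 among the tumours; it was detected on 1 of 5 of the 3-month livers, so this value starts at background and is rough. Cpe (6.00, adjusted p = 2.02e-06), Tspan8 (5.88, adjusted p = 2.29e-05), Cbr3 (5.65, adjusted p = 1.80e-05), Akr1c18 (5.48, adjusted p = 2.26e-06) and Gstp2 (5.15, adjusted p = 1.62e-06) rose again, and so did Tceal5, an X-linked transcription elongation factor relative, at least 24.4-fold (adjusted p = 4.71e-06). Hsd3b5 fell by 7.23 (SE 0.17, adjusted p = 1.52e-10), Serpina4-ps1 fell by 7.17, Mup9 fell by 5.68 and Sult2a8 fell by 5.59. Cfd (the complement protease adipsin) fell by 5.27, Mup4 fell by 4.99, Susd4 fell by 4.87, Cyp4a12b fell by 4.67 and Cyp4a12a fell by 4.64. Elovl3 was at least 21.7-fold lower. Spink1 and Cpe were detected on 2 of the 5 E545K livers of 3 months, and Hsd3b5 on 1, Susd4 and Cfd on 2 and Sult2a8 on 3 of the 5 tumours, so these folds too reach down to background. Pik3ca did not pass (0.35, adjusted p = 0.238).

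Of the 14 gene lists called here and the 14 called against the 3-month controls, 13 were called in both in the same direction; periportal genes were called only against the controls and fatty acid oxidation only here. With fry 15 lists were called. Male-biased genes (median -3.11, 10 of 12 lower, adjusted p = 1.53e-09, adjusted p = 0.0473 with an estimated correlation) and oncofetal genes (2.76, 12 of 17 higher, adjusted p = 5.80e-07, adjusted p = 0.0203 with an estimated correlation) passed either way. Pericentral genes (-2.27, adjusted p = 1.02e-06, adjusted p = 0.359 with an estimated correlation), macrophage markers (1.59, adjusted p = 2.85e-06, adjusted p = 0.359 with an estimated correlation) and acute-phase genes (1.09, adjusted p = 1.44e-07, adjusted p = 0.0531 with an estimated correlation) passed at the preset correlation, and so did fatty acid oxidation (-0.70, 11 of 20 lower and 1 higher, adjusted p = 0.00301, adjusted p = 0.398 with an estimated correlation).

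With the 6-month controls the tumours had 2309 genes past the threshold, 1274 higher and 1035 lower, and over all tested genes 1694 had groups that did not overlap (chance 0.794%). Called against both ages of control were 1102 higher and 889 lower genes; both comparisons use the same tumour arrays, so overlap arises from the shared arm as well. Lcn2 (7.95, SE 0.35), Spink1 (7.39, SE 0.52), Gpc3 (5.73) and Akr1c18 (at least 90.6-fold) were higher, and Hsd3b5 (-7.28, SE 0.19), Car3 (carbonic anhydrase of muscle and liver, -4.43) and Elovl3 (at least 17.7-fold) lower. Gpc3 was detected on 2 and Spink1 on 3 of these 5 controls, so their rises start near background and are rough. Oncofetal genes (adjusted p = 0.0120 with an estimated correlation) and male-biased genes (adjusted p = 0.00308 with an estimated correlation) again passed either way, and 13 lists passed at the preset correlation and 16 with fry.

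Liver 3 months after H1047R had higher medians of lipid-storage and NRF2-target lists at the preset correlation, but no single gene passed and no list was called with an estimated correlation or with fry. limma called 0 of 11594 genes (smallest adjusted p = 0.130), where 812 had an unadjusted p under 0.05 and 440 had groups that did not overlap (chance 2.86%). Cidea, which fuses lipid droplets, was detected on 4 of 4 H1047R and 0 of 4 control arrays and was at least 23.1-fold higher, though with an SD of 2.71 and an adjusted p = 0.428 (0.00620 over the list alone). It was detected also on 4 of 5 E545K livers of 3 months and on 2 of 5 controls of 6 months. Cidec, its relative, had 2.54 (0.00620 over the list alone), Plin4, a droplet coat protein, 1.07, and Mogat1, a monoacylglycerol acyltransferase, 0.84. The list of lipid droplet and PPAR gamma targets had a median of 0.54 with 0 of 13 genes past the threshold over all genes and 2 over the list alone (adjusted p = 5.20e-04, adjusted p = 0.356 with an estimated correlation). NRF2 targets had 0.34 with 0 of 12 and 3 over the list alone (adjusted p = 5.20e-04, adjusted p = 0.356 with an estimated correlation), with Abcc4, an efflux pump (1.01, SE 0.14, adjusted p = 0.130; 2.68e-04 over the list alone), Cbr3 (1.58; 0.0187) and Nqo1 (0.41; 0.0360).

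Lists of lipid synthesis and the pentose phosphate pathway had higher medians and sterol synthesis a lower one in the H1047R livers, with no member past the threshold over all genes. Without 3-month controls 1 and 2 the cholesterol median turned to 0.070, lipid droplet genes had -0.0023 (adjusted p = 0.284) and de novo lipogenesis 0.043 (adjusted p = 0.266), and mature hepatocyte genes lost their call (adjusted p = 0.0682). Single samples ended calls too: de novo lipogenesis without H1047R replicates 1 or 4 or control replicate 1, and cholesterol synthesis without H1047R replicates 2 or 3 or control replicates 1 or 2. The same holds for stellate cell and matrix genes without H1047R replicate 1 or control replicates 1 or 3, and for mature hepatocyte genes without H1047R replicate 2 or control replicate 3. De novo lipogenesis had a median of 0.27 (adjusted p = 0.0193, adjusted p = 0.788 with an estimated correlation), with values of 2.22 for Pnpla3, 1.51 for Thrsp and 1.34 for Elovl6. The pentose phosphate list had 0.39 with 0 of 6 over all genes and 2 over the list alone (adjusted p = 0.00761, adjusted p = 0.356 with an estimated correlation), namely Rpia (0.84; 0.00178 over the list alone) and Taldo1 (0.43; 0.0174). Cholesterol synthesis had -0.17 (adjusted p = 0.0168, adjusted p = 0.808 with an estimated correlation), with -1.13 for Idi1, -0.52 for Lss and -0.51 for Nsdhl. Endothelial markers had 0.27 (adjusted p = 8.44e-04, adjusted p = 0.356 with an estimated correlation; Vwf 0.54, Plvap 0.49, Tie1 0.41, Eng 0.39). Stellate cell and matrix genes had 0.16 (adjusted p = 0.0234, adjusted p = 0.571 with an estimated correlation) with Vim, a filament protein of mesenchyme, at 0.79 (0.00381 over the list alone). Mature hepatocyte genes had -0.11 (adjusted p = 0.00985, adjusted p = 0.356 with an estimated correlation; Alb -0.85, Fgb -0.85, Serpinc1 -0.49). The PI3K-AKT-mTOR list had 0.02 (adjusted p = 0.893). Without the 3-month control and the H1047R liver that carried the highest muscle means (control replicate 4 and H1047R replicate 2, left out after the data were seen), 14 lists were called in place of 8.

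The single genes of smallest p, none of which passed, were on the higher side Abcc4, Klf2 (an endothelial flow factor, 0.997), Vim, Pcmtd1 (0.77) and Rpia (ribose 5-phosphate isomerase, 0.84). On the lower side they were Gbp11, a guanylate-binding protein (-1.10, SE 0.14, adjusted p = 0.130), Rell1 (-0.75), Plk3 (a stress kinase, -0.97), Dnmt3b (a DNA methyltransferase, -1.08) and Got1 (aspartate aminotransferase, -0.80). Pik3ca had 0.18 (adjusted p = 0.812). Without H1047R replicate 1 limma called 1 gene and without replicate 4 it called 2, against 0 with all arrays.

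Liver 3 months after E545K had lower Apoa4, the apolipoprotein of lipid-laden liver and gut, and lists called only at the preset correlation (9, against 0 with an estimated correlation and 0 with fry), none with a member past the threshold over all genes. Apoa4 fell by 1.83 (SE 0.20, adjusted p = 0.0167) and was the 1 of 11594 genes that passed. At the same time 536 genes had an unadjusted p under 0.05 and 194 had groups that did not overlap (chance 1.59%). Both counts are near what chance gives over 11594 genes. A further probe of Apoa4 had a larger fall and an adjusted p of 0.215 when each probe was tested. Leaving out E545K replicates 1, 3 or 5 or any one of the 4 controls left 0 genes called, as did leaving out controls 1 and 2, whose acute-phase means were the highest, together. Pik3ca had 0.23 (adjusted p = 0.9999).

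The clock list had a median of 0.35 with 0 of 11 genes past the threshold over all genes and 4 over the list alone, 2 higher and 2 lower (adjusted p = 0.0130, adjusted p = 0.492 with an estimated correlation). The output factors Dbp (2.32, adjusted p = 0.188; 4.47e-04 over the list alone) and Tef (1.22, adjusted p = 0.164; 4.47e-04) had higher values, and the opposed factors Arntl (-1.004, adjusted p = 0.596; 0.00121) and Nfil3 (-0.88; 0.00212) lower ones. The difference between Dbp and Arntl ran from 5.19 to 7.77 in the E545K livers and from 2.29 to 4.00 in the 3-month controls, but from 2.00 to 8.28 over the 6-month controls. Pericentral genes had a median of 0.20 (adjusted p = 0.00345, adjusted p = 0.589 with an estimated correlation), with Tbx3 at 0.80, Lgr5 at 0.53, Rgn at 0.46 and Rnf43 at 0.44. Periportal genes had -0.19 (adjusted p = 0.0130, adjusted p = 0.589 with an estimated correlation), with the amino acid enzymes Sdsl at -0.78, Sds at -0.75 and Gls2 at -0.41. Fatty acid oxidation had 0.18 (adjusted p = 0.00345, adjusted p = 0.589 with an estimated correlation; Fgf21 0.96, Acot1 0.60, Ehhadh 0.55). De novo lipogenesis had 0.14 (adjusted p = 0.0277, adjusted p = 0.589 with an estimated correlation; Thrsp 0.93, Fasn 0.75 with 0.0403 over the list alone) and the pentose phosphate list 0.14 (adjusted p = 0.0277, adjusted p = 0.492 with an estimated correlation; Rpia 0.59 with 0.0328 over the list alone).

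The acute-phase list had a lower median in the E545K livers, with 0 of 18 members past the threshold over all genes (-0.25, adjusted p = 0.0130, adjusted p = 0.618 with an estimated correlation; Lcn2 -1.61, Orm2 -0.63), where 3-month controls 1 and 2 had acute-phase means of 10.8 and 10.5 in a group mean of 9.97. Macrophage markers had -0.26 (adjusted p = 0.0440, adjusted p = 0.662 with an estimated correlation; Gpnmb -0.74, Cd68 -0.56, Csf1r -0.38) and mature hepatocyte genes -0.15 (adjusted p = 0.0264, adjusted p = 0.492 with an estimated correlation; Tat -0.44). Without these controls 3 lists were called in place of 9, and the medians of acute-phase genes (0.16), fatty acid oxidation (-0.12) and macrophage markers (0.035) turned. None of the 9 kept its call there in its direction: the clock (0.38, adjusted p = 0.0629), pericentral (0.12, adjusted p = 0.373), periportal (-0.12, adjusted p = 0.253), de novo lipogenesis (0.045, adjusted p = 0.462), pentose phosphate (0.062, adjusted p = 0.253) and mature hepatocyte (-0.12, adjusted p = 0.160) lists did not pass. Leaving out any one of the 9 samples ended the call of at least 1 list, that of the clock without E545K replicate 4 (adjusted p = 0.119); without E545K replicate 2 there were 4 and without 3-month control replicate 2 there were 5. The PI3K-AKT-mTOR list had -0.02 (adjusted p = 0.703).

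E545K and H1047R livers of 3 months differed in no single gene, and in stromal and lipid lists at the preset correlation (6 lists) but not with an estimated correlation (0 lists). With fry 1 list was called, proliferation (adjusted p = 0.0164). limma called 0 genes (smallest adjusted p = 0.671), with 713 at an unadjusted p under 0.05 and 263 with groups that did not overlap (chance 1.59%). The lists called had lower medians after E545K. Macrophage markers had -0.44 (adjusted p = 2.19e-04, adjusted p = 0.501 with an estimated correlation; Gpnmb -1.21, C1qb -0.78, Trem2 -0.61) and stellate cell and matrix genes -0.36 (adjusted p = 6.63e-05, adjusted p = 0.501 with an estimated correlation; Acta2 -0.998, Tgfb1 -0.58 with 0.0427 over the list alone). Lipid droplet genes had -0.30 (adjusted p = 0.0172, adjusted p = 0.511 with an estimated correlation; Cidea -3.54) and NRF2 targets -0.27 (adjusted p = 0.00292, adjusted p = 0.501 with an estimated correlation; Cbr3 -1.62 with 0.0133 over the list alone). Endothelial markers had -0.22 (adjusted p = 2.34e-04, adjusted p = 0.420 with an estimated correlation; Cd34 -0.59 with 0.0323, Eng -0.47 with 0.0308) and proliferation genes -0.08 (adjusted p = 0.0212, adjusted p = 0.420 with an estimated correlation; Mcm2 -0.54, Mcm7 -0.48). Without H1047R replicate 4 there were 15 lists in place of 6. Lipid droplet genes lost their call without E545K replicate 2 (adjusted p = 0.194) or H1047R replicates 1 or 3, and proliferation without E545K replicate 4 or H1047R replicate 3. The genes of smallest p that did not pass were Ric1 (0.64), Frrs1 (0.70), Prkar2a (a protein kinase A subunit, 0.73), Cyp2a4 (1.48) and Slc5a6 (a vitamin transporter, 0.77) with higher values after E545K. With lower values they were Hipk2 (a stress kinase, -0.73), C1qtnf12 (-0.81), Cyp4a12b (-0.60), Fbln2 (a matrix protein, -0.74) and Cdkn1a (the cell cycle inhibitor p21, -1.53). Pik3ca had 0.05 (adjusted p = 0.979).

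Fold changes of the mutations at 3 months correlated at 0.555 over 11594 genes, with 65.7% of the same sign, but they share their controls. Simulated arrays with no change gave 0.528 (0.485 to 0.564) and 67.7%, and with the controls split between the mutations the mean was 0.0980 (-0.0386 to 0.234 over 6 assignments). The covariance of 0.0386 exceeded the 0.0313 that shared controls give by 0.00728. When whole arrays were resampled with no change, covariances ran from -0.0174 to 0.146 and correlations from -0.433 to 0.942, so the observed values lie inside and no agreement beyond the shared controls is shown.

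The H1047R livers of 6 and 12 months shared the loss of Hsd3b5 and the gain of Cyp2b9 with the E545K tumours, and the 12-month tumour carried most of the rest of the tumour profile. Against the 6-month controls 5 genes passed. Cyp2b9 rose by 5.45 (SE 0.31, adjusted p = 3.67e-04), Ttc39a, a tetratricopeptide protein, by 3.17 (adjusted p = 0.0163). Both were detected on 1 of 5 controls, so their rises start near background and are rough. Sdcbp2 (a syntenin) was higher at least 8.42-fold (adjusted p = 0.0480) and Cyp2b23 at least 5.10-fold (adjusted p = 0.0152). Hsd3b5 fell by 5.89 (SE 0.32, adjusted p = 3.67e-04). Pik3ca had -0.28 (adjusted p = 0.894). With n of 2 and 5, 1037 genes had an unadjusted p under 0.05, 1356 had groups that did not overlap (chance 9.52%), and on simulated data the same sizes recovered 1 of 100 genes changed by log2 1 and 48 of 100 changed by log2 2. Without the 6-month H1047R liver 839 genes were called and without the 12-month tumour 3; without 6-month control replicates 1 or 4 there were 3 and without replicates 2, 3 or 5 there were 2.

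Male-biased genes had a median of -1.74 (1 of 12 lower over all genes, 8 over the list alone; adjusted p = 5.53e-14, adjusted p = 0.141 with an estimated correlation), with Cyp7b1 (-2.86; 0.00250 over the list alone), C8b (-2.38) and Cyp4a12b (-2.35). P450 and bile acid genes had -1.46 (adjusted p = 3.47e-08, adjusted p = 0.176 with an estimated correlation). Periportal genes had -1.32 (adjusted p = 5.58e-05, adjusted p = 0.220 with an estimated correlation; Cps1 of the urea cycle -2.81, 0.0411 over the list alone) and mature hepatocyte genes -0.75 (adjusted p = 6.99e-07, adjusted p = 0.141 with an estimated correlation; Tdo2 -1.90). Stellate cell and matrix genes had 1.60 with 0 genes over all genes and 7 over the list alone (adjusted p = 4.01e-10, adjusted p = 0.176 with an estimated correlation), with Timp1 (4.57; 0.0285 over the list alone), Fbn1 (2.71) and Tgfb1 (1.45). Lipid droplet genes had 0.85 (adjusted p = 0.00116, adjusted p = 0.141 with an estimated correlation), with Apoa4 (2.79; 0.00154 over the list alone), Vldlr (2.39; 0.00330) and Cidea (4.87; 0.0185). Glycolysis had 0.41 (adjusted p = 0.00120, adjusted p = 0.236 with an estimated correlation), with hexokinase Hk2 (3.89; 0.00808). limma called 17 lists here, 8 without the 12-month tumour and 0 with an estimated correlation; fry called 4, those of male-biased, female-biased, mature hepatocyte and lipid droplet genes. Most of these medians rest on the 12-month tumour: at 12 and 6 months alone they were -2.64 and -0.84 for male-biased, -2.19 and -0.19 for P450 and bile acid, -2.60 and -0.073 for periportal and -0.79 and -0.48 for mature hepatocyte genes, 2.36 and 0.79 for stellate cell and matrix genes and 1.09 and 0.065 for glycolysis. Lipid droplet genes had 0.26 and 1.24. Periportal genes and glycolysis did not pass without the 12-month tumour, and lipid droplet genes did not without the 6-month liver.

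As single livers the late H1047R samples were unlike each other. Relative to the mean of the 6-month controls, Hsd3b5 was at -6.24 in the tumour of 12 months and -5.53 in the liver of 6 months, Cyp2b9 at 5.26 and 5.64, Cps1 at -2.87 and -2.74, Cidea at 5.52 and 4.21 and Apoa4 at 3.09 and 2.49. Lcn2 was at 8.07 and -0.08, Spink1 at 6.06 and -0.63, Golm1 at 4.80 and 0.14, Spp1, the cytokine osteopontin, at 5.69 and 0.28, and Oat at -4.73 and -0.07. The pericentral median was -2.21 at 12 months and 0.44 at 6 months and that of fatty acid oxidation -1.16 and 0.42. Unlike the E545K tumours, the 12-month tumour had Gpc3 at 0.29 and H19 at 0.54. Over 11594 genes its changes correlated with those of the E545K tumours at 0.742, those of the 6-month liver at -0.240, where single 6-month controls against the other controls gave -0.282 to 0.307, so the value of the 6-month liver is within what a control gives. Of the 4689 genes called in the E545K tumours 91.0% had the same sign in the 12-month tumour and 28.4% in the 6-month liver. Genes at least 2-fold from the control mean numbered 2291 and 1167, where single 6-month controls against the other controls gave 244 to 1536. Lcn2, Spink1, Golm1, Spp1, Oat, Gpc3 and H19 were picked out here after their values were seen.

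**Figure D4:**
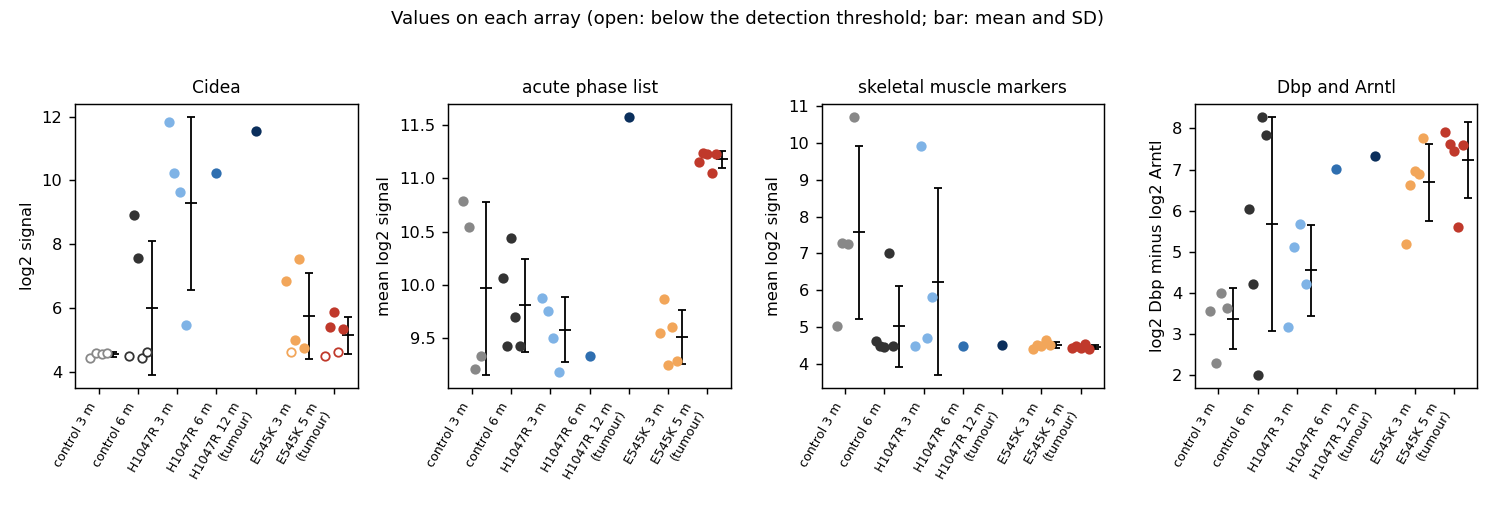
Cidea, the mean of the acute-phase list, the mean of the skeletal muscle markers and the difference between Dbp and Arntl (log2 signal, vertical axes) on each array by group; points are arrays. Single arrays stand apart within groups, such as 3-month control 4 with a muscle mean of 10.7 and 3-month control 1 with an acute-phase mean of 10.8.

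Controls of 6 and 3 months differed in 2 genes. Rgs16 rose by 4.05 (SE 0.48, adjusted p = 0.0266; detected on 5 of 5 and 3 of 4 arrays) and Fam83f fell by 1.78 (SE 0.21, adjusted p = 0.0266; detected on 2 of 5 and 4 of 4). At an unadjusted p under 0.05 there were 1235 genes. limma called 0 of 29 lists (smallest adjusted p = 0.203), fry also 0, and Pik3ca had 0.47 (adjusted p = 0.442). Leaving out 6-month control replicates 1, 3 or 4 or 3-month control replicate 1 left 1 gene, and leaving out any other control left 0.

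The authors' deposited table named for E545K at 5 months against controls of 3 months holds differences that match the tumours minus the 6-month controls (correlation 0.9998) rather than minus the 3-month controls (0.886). At an adjusted p under 0.05 the authors' deposited table of this comparison holds 4343 probes, 2402 higher and 1941 lower, with 1792 at least 2-fold. In the authors' deposited tables for the 6-month controls, E545K at 3 months and H1047R at 3 months, each against the 3-month controls, 0 probes pass and the smallest adjusted p values are 0.115, 0.816 and 0.186.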

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

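The tests on clock genes were chosen only after the result was seen, while the counts of splits and the search for samples far from their group were planned.

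Over 155 groups and measures, 9 held a sample far from the others of its group, where chance gives about 1 in 20. Gaps relative to the range of the group were 0.843 for proliferation genes, lowest in H1047R 3 months replicate 2, and 0.816 for the same genes, lowest in 6-month control 1. Periportal genes gave 0.898 for H1047R 3 months replicate 1 as the lowest and 0.758 for E545K tumour 2 as the highest. Y-linked genes gave 0.744 for E545K tumour 4 as the highest, and macrophage markers 0.863 for 3-month control 1 as the highest. Endothelial markers gave 0.897 for H1047R 3 months replicate 3 and erythroid markers 0.752 for 6-month control 5, each as the lowest. The clock list gave 0.796 for E545K tumour 4 as the lowest.

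The clock list was called between E545K livers and controls of 3 months (median 0.35) with 0 of 11 genes past the threshold over all genes. It was not called with an estimated correlation (adjusted p = 0.492), without E545K replicate 4 (adjusted p = 0.119) or without controls 1 and 2 (adjusted p = 0.0629). An effect of the E545K construct stays open: the Dbp minus Arntl differences of E545K livers (from 5.19) and 3-month controls (to 4.00) do not overlap, and that 3 of 5 of the 6-month controls reach 5.19 shows a wide spread without a construct but excludes nothing at 3 months. A candidate explanation is the hour of tissue collection: genes that peak with Dbp lay 1.52 above those that peak with Arntl (7 and 3 genes), a gap that 0.0177 of random assignments of the genes reached. These are the genes and arrays that gave the result, so the gap is no separate evidence. The labels give no hour, so the hour of collection stays a hypothesis.

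Between the mutations at 3 months limma called 0 genes (713 at an unadjusted p under 0.05), and 6 lists were called at the preset correlation but 0 with an estimated correlation and 1, proliferation, with fry. E545K against H1047R had list medians of -0.30 for lipid droplet genes, -0.27 for NRF2 targets, -0.080 for proliferation, -0.36 for stellate cell and matrix genes, -0.44 for macrophage markers and -0.22 for endothelial markers. The tumours differed from E545K livers of 3 months in 4725 genes.

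Chance as the source of the gene counts can be excluded for the tumours. Against the 3-month controls 1 of 100 splits gave as many genes as the real split, which is itself (real 4689, highest other 4200), and against E545K at 3 months again 1 of 100 splits (real 4725, highest other 1). The split with 4200 genes sets tumours 2 to 5 against tumour 1 with the controls, so it carries most of the real difference. For E545K at 3 months 3 of 100 splits gave as many genes (real 1, highest other 3), and for the controls of both ages 3 of 100 splits (real 2, highest other 963). By share alone both passed the test against chance, but in both another split gave more genes than the real one. The counts are of 1 and 2 genes whose calls end under several of the other settings, so chance is not excluded for them. The split with 963 genes, several times the real count, points to a structure of the controls other than age: it sets 6-month controls 1 and 4 with 3-month controls 1, 2 and 4 against the rest. For H1047R at 3 months 35 of 35 splits (real 0, highest other 1) and for E545K against H1047R 100 of 100 splits (real 0, highest other 2) gave as many genes. A real count of 0 fixes this in advance, so there is no count to set against chance.

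For counts of gene lists the splits exclude chance in none of the comparisons, but for the tumours they cannot decide. The splits with 17 lists set tumours 1, 2, 3 and 5, with 3-month control 4 or E545K 3 months replicate 2, against the rest. They carry most of the real difference, so the shares for the tumours are not chance rates. As many lists came from 8 of 35 splits for H1047R at 3 months (real 8, highest other 15), 10 of 100 splits for E545K at 3 months (real 9, highest other 13), 11 of 100 splits for the tumours against 3-month controls (real 14, highest other 17) and 12 of 100 splits against E545K at 3 months (real 14, highest other 17). For the controls of both ages 100 of 100 splits (real 0, highest other 11) and for E545K against H1047R 32 of 100 splits (real 6, highest other 15) gave as many. For the controls a real count of 0 fixes this in advance.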

How the results depend on the processing

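Leaving out the arrays with the highest muscle or acute-phase means was chosen after seeing the data; the other alternatives were planned. Counts of genes for H1047R at 3 months (0) and E545K against H1047R (0) stayed at 0 under all alternatives, except that leaving out single samples gave 0 to 2 for the former. The tumours against the 3-month controls (4689) gave 3603 to 5624 genes, and 3809 to 5404 with single samples left out. With every detected probe on its own 6799 probes passed. Only 2309 genes passed with the 6-month controls in place of those of 3 months, and 2810 without the 2 controls of highest acute-phase signal. Against E545K at 3 months (4725) the count of genes ran from 4254 to 6193 and with single samples left out from 3804 to 5367, and 6622 single probes passed. For E545K at 3 months (1) the count was 0 with no filter on dim probes, with all 25 arrays in 1 fit, without the 2 arrays with most muscle signal and without the 2 controls with most acute-phase signal, 2 for every detected probe and for eBayes with trend and robust, 3 with array weights, and 0 to 1 with single samples left out. For the controls of both ages (2) it was 0 with no background correction, the authors' processed values, no filter, all 25 arrays in 1 fit and without the arrays of most muscle or acute-phase signal, 1 with array weights, and 0 to 1 with single samples left out. The late H1047R livers (5) gave 2 with no background correction, the authors' processed values or array weights, 10 with trend and robust, 64 with the 9 controls of both ages, 594 with all 25 arrays in 1 fit, 1097 with the livers as 2 groups in that fit, and 2 to 839 with single samples left out, where a lone sample is assumed to vary like the controls. Gene lists called over all comparisons (68) were 3 with an estimated correlation, 39 with fry, 60 to 79 at the preset correlation under the other settings and 59 to 77 with single samples left out. The correlation of the mutations (0.555) stayed within 0.388 to 0.669 with single samples left out and was 0.680 without the 2 controls with most acute-phase signal. The cause of these differences was not tested.

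Same replicate numbers gave no clear sign of pairs, though pairing is not excluded. Over the comparisons with both groups numbered, correlations of residuals between same-number samples ran from -0.306 to 0.410. In 6 of 25 cases the sample of the same number was the best match. With the replicate block the counts were 0 for H1047R at 3 months, 0 for E545K at 3 months, 3603 and 4504 for the tumours against 3-month controls and E545K at 3 months, 0 for the controls of both ages, 0 for E545K against H1047R and 71 lists. No block fit was made for the late H1047R livers, which share too few numbers with their controls. The chip as a block was not run, since no source used here gives the chip.

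Reversed medians came mostly without the 2 controls with most acute-phase signal: H1047R at 3 months 0.31 for acute-phase genes, 0.070 for cholesterol synthesis and -0.23 for fatty acid oxidation; E545K at 3 months 0.16, 0.15 and -0.12 for the same lists and 0.035 for macrophage markers; the 6-month controls 0.52 for acute-phase genes. Without 3-month control replicate 1 the macrophage list of E545K at 3 months had a median of -0.046 and a test pointing up, so median and test differ in sign; with single samples left out its median ran from -0.35 to -0.046. Without the 12-month H1047R tumour the late list medians were 0.42 for fatty acid oxidation and 0.44 for pericentral genes, those of the 6-month liver alone, and without that liver -1.16 and -2.21. Over named genes and alternatives, 15707 cases kept direction and side of the threshold, with 346 weaker, 185 stronger and 174 moved, and list results did so in 3270, with 174 weaker, 122 stronger and 164 moved. Arrays with weak signals limit what is seen: detected probes ran from 14536 to 18391.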

Other observations

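The tests on the sex-biased genes by Y-linked genes, by hepatocyte share and in the late livers, the test of muscle genes against the E545K construct, and all gene families were chosen only after the result was seen.

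Gene families, grouped by the stem of their symbols with at least 8 tested members (185 families, 3733 genes), were tested in the E545K tumours; 6 passed against the 3-month controls and 8 against the 6-month controls. Lower with both were cytochromes P450 (Cyp), 27 of 65 (Fisher's exact adjusted p = 0.0125) and 21 of 65 (Fisher's exact adjusted p = 1.86e-05), and genes of the Nat stem, 7 of 9 (Fisher's exact adjusted p = 0.0263) and 6 of 9 (Fisher's exact adjusted p = 0.00296). Against the 3-month controls 21 of 39 Rpl genes of the large ribosomal subunit were higher (median 0.48, Fisher's exact adjusted p = 6.59e-04), such as Rpl7 (2.04) and Rpl18 (1.37), and 7 of 8 Cxcl chemokines were higher (median 1.23, Fisher's exact adjusted p = 0.0125), led by Cxcl1 (3.14) and with Cxcl12 falling (-0.83); with the 6-month controls 5 of 8 were higher (Fisher's exact adjusted p = 0.0309). Lysine methyltransferases of the Kmt stem were lower in 7 of 8 cases (median -0.84, Fisher's exact adjusted p = 0.0125), among them Kmt5c (-1.66) and Kmt2c (-1.07), and chromatin remodellers of the Chd stem in 7 of 9 (Fisher's exact adjusted p = 0.0263), with Chd3 (-1.71). With the 6-month controls 0 of 8 Kmt genes passed and 9 of 39 Rpl genes were higher (Fisher's exact adjusted p = 0.425), and 1 of 9 Chd genes was lower, so the calls of the Rpl, Kmt and Chd families depend on the control group. The Chd median kept its direction (-0.44 with the 6-month and -0.58 with the 3-month controls).

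With the 6-month controls 10 of 14 carboxylesterases (Ces) were lower (median -1.24, Fisher's exact adjusted p = 8.18e-06), led by Ces3b (-4.44), Ces3a (-3.51) and Ces1e (-3.25), while Ces2g (1.67) and Ces2e (1.41) rose. Of 8 annexins, calcium-dependent membrane binders, 6 were higher (Fisher's exact adjusted p = 0.00296), with Anxa2 (3.23) and Anxa5 (2.51), and 5 of 8 Toll-like receptors (Fisher's exact adjusted p = 0.0309), with Tlr1 (2.30) and Tlr2 (2.07). Lower were 6 of 10 Ndufb subunits of respiratory complex I (Fisher's exact adjusted p = 0.00472) and 8 of 16 Atg autophagy genes (Fisher's exact adjusted p = 0.00296), with Atg16l2 (-1.51). Against the 3-month controls none of these 5 families passed (Fisher's exact adjusted p = 0.411 for Ces, 0.0538 for annexins and Ndufb, 0.316 for Toll-like receptors and 0.597 for Atg), though medians were of like size for annexins (1.28, and 1.26 with the 6-month controls), Toll-like receptors (1.07 and 0.97) and Ndufb (-0.94 and -0.77). Medians of the families named kept their sign without background correction and with the authors' values, but some shrank by over 1.5-fold. Without background correction and with the authors' values they were 0.65 and 0.67 for Cxcl, -0.12 and -0.13 for Cyp (-0.40 with background correction), -0.61 and -0.61 for Nat (-1.05) and -0.39 and -0.40 for Chd (-0.58) against the 3-month controls. Against the 6-month controls they were -0.74 and -0.75 for Ces, 0.34 and 0.36 for Toll-like receptors, 0.58 and 0.60 for Cxcl (1.15), -0.25 and -0.25 for Cyp (-0.41) and -0.32 and -0.33 for Nat (-0.97).

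Male-biased genes were lower and female-biased genes higher in the E545K tumours. Female or mixed-up mice are argued against by the Y-linked genes, which lay at -0.34 relative to the controls and between 7.32 and 7.56 on the tumour arrays. Background correction as the source is argued against by the male-biased median (-3.28 as reported). It stayed at -2.85 or lower without that correction and with the authors' values. All of these values have the same distribution on each array, so normalization itself was not tested. Fewer hepatocytes would not raise female-biased genes, but these had a median of 2.26. Their mean was 5.07 in the 3-month controls, near background, so they had little room to fall, and their rise does not bear on the male-biased part. Male-biased genes lay -3.17 from mature hepatocyte genes. The 95% interval of -4.98 to -1.64 comes from resampling the genes of both lists with the arrays held fixed. It does not measure the spread between samples. A change that goes with late PIK3CA-driven lesions of either mutation stays open for the male-biased part: in the late H1047R livers its median (-0.84 and -2.64) lay below those of single 6-month controls against the others (-0.23 to 0.31). Percentiles among random lists say less, since 1 of these 5 controls reached 0.63. For the female-biased part nothing was settled: its medians of 0.26 and 0.37 lay little above the single controls (-0.32 to 0.17) and at percentiles 85.3 and 89.7 of random lists. A loss of male-biased expression with late lesions may be biological, as a hypothesis found and tested on the same data, with 1 liver at each late age.

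Skeletal muscle genes were high on some arrays of the 3-month controls and H1047R livers: the marker mean was 10.7 on 3-month control 4, 9.93 on H1047R 3 months replicate 2, and 4.40 to 7.28 on the other arrays. A fall of muscle genes through the E545K construct stays open: E545K livers (to 4.65) and controls (from 5.03) of 3 months do not overlap, and that 1 of 5 of the 6-month controls lay above all E545K livers of 3 months excludes nothing at 3 months. The H1047R livers of 3 months, without E545K, were at 4.49 and 4.70 (replicates 1 and 3) and at 9.93 and 5.83 (replicates 2 and 4). The 6-month controls 1, 2, 3 and 5 were at 4.47 to 4.63. Means near those of the E545K livers thus occur without that construct. They lie near the lowest detected signals of the arrays (4.59 to 4.93), so the E545K livers had little or no muscle signal, as on most other arrays. Skeletal muscle tissue in the liver samples could not be settled by the share of further markers that followed the first ones. It was 0.55 (11 of 20), where the test had asked for more to accept it and for fewer to exclude it. Of those that followed, Myh2 (correlation 0.990, highest 11.6), Tcap (0.986, 10.3) and Cox6a2 (0.933, 12.0) were highest on 3-month control 4. Among those that did not were Ttn (-0.064), which stayed near background (at most 5.21), and Tpm1 (-0.238). The 3-month comparisons stand with this open.

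Untested lists had too few members: B and plasma cells 3, adipocytes 3 and exocrine pancreas 1, with tumour medians against the 3-month controls of 0.28, -0.74 and 0.65.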
